A study of Rattus norvegicus with 29 samples.

How the data were processed

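Liver RNA of 29 rats was hybridised to Affymetrix whole-transcript arrays, 1 array per animal, per the labels' protocols. The authors deposited 1 table of log2 values for 27342 transcript clusters. In that deposited table each row has a median of 0 over the 29 arrays. The submitters' processing notes name PLIER and MAS5, without versions or roles. The step that normalized between arrays, the centring and any offset added before the log are not given in the sources used here. Of the rows, 27332 held values on the rounding grid that single-precision numbers of 4 or more would leave, and the other rows had fewer than 10 entries with enough decimals to judge. A grid that fits stored values of 8 or more in all animals was found for 7792 rows. A positive offset before the log would make folds of dim genes too small, and expression levels were not recoverable. Slide and scan date were not used here, so batches were not tested. Animals dosed with 200 mg/kg and killed at day 8 were not analysed here.

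Gene names came from the platform annotation of the array. It gave 1 gene symbol for 15097 clusters, several for 323 and none for 11922, and clusters with several symbols are not named. The single symbols covered 14324 genes. For a gene with more than 1 cluster, the cluster with stored values of 8 or more was taken first, then the lowest probe number, because the planned choice by highest mean level could not be made on centred values. Gsta2 lay in a cluster shared with another gene, so it is not given. A further gene chosen in advance is not reported here. Of the clusters with 1 symbol, 15067 had a gene identifier found in the reference gene table (assembly GRCr8), and 0 symbols differed there.

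Comparisons were tested with limma 3.58.1 in R 4.3.3 on the log2 values as deposited: a linear model with 5 groups over all 29 animals, empirical Bayes moderation without a trend, and Benjamini-Hochberg adjustment over all clusters within a comparison, with a threshold of 0.05. P-values are two-sided. Before the data were examined, the comparisons, 38 gene lists and the rule for named genes were fixed. For each comparison with vehicle the rule took the 10 largest rises and 10 largest falls among called clusters with 1 symbol that is not provisional and every treated animal on the same side of the vehicle mean, a fixed set of genes given whatever their change, up to 4 called members of each list that passed camera and up to 2 of each other list. For the other comparisons it took the 5 largest in each direction, for the interaction without the condition on sides. The text names a part of the list members. Values of Slc13a5, Akr1b8, Akr1b7, Acot1, Ces2e, Nat8 and Igfbp1 at single doses or days, and of Cyp2b1 between doses, stand outside the rule and were chosen after their values were seen. Intervals of 95% use the t quantile of the moderated fit. A further 3 lists (immediate early genes, carboxylesterases, and amino acid transporters and synthetases) were put together after the values were seen.

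Lists were tested with camera at a preset correlation of 0.01 between genes, with an estimated correlation and fry as alternatives. On simulated unchanged data for 2000 mg/kg against vehicle at day 29, the preset correlation called a median of 7 and up to 20 of 38 lists, and the estimated one called 0, so the calls given with an estimated correlation are the firmer ones. The limma step was tested on simulated data of 27342 clusters. For 2000 mg/kg at day 8 it recovered 90.9% of changes of 0.5 on the log2 scale, 99.3% of changes of 1 and 100% of changes of 2. For 2000 mg/kg at day 29 these shares were 91.5%, 99.6% and 100%, and for 200 mg/kg 88.4%, 99.6% and 100%. The changed clusters were drawn at random from all clusters, so the shares can be lower for genes that vary more between animals.

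The highest correlation between any 2 arrays was 0.73, and no pair of arrays looked like 1 sample deposited more than once. Alternatives covered quantile normalization, centring of each array, clusters with 1 symbol only, only the animals of the groups compared, trend and robust settings, array quality weights, the replicate number as a block, stricter thresholds and leaving out each animal. Added after seeing the data were clusters with stored values of 8 or more, leaving out vehicle day 29 replicates 1 and 2 together, and the mean of the immediate early genes or of the macrophage markers as a covariate. Overlaps between comparisons with shared vehicle animals were set beside 100 simulations for the correlation and 20 for the shared calls. Exact permutation tests were used for means per animal. Plots were drawn with matplotlib 3.10.9.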

Results

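Liver RNA was profiled in male Sprague-Dawley rats dosed by oral gavage with 2,2,5,7,8-pentamethyl-6-chromanol (PMCol), a chromanol related to vitamin E that lacks its long side chain, or with the methylcellulose vehicle. Animals received 7 daily doses and were killed on day 8, or 28 daily doses and were killed on day 29. The groups were vehicle at day 8 (n = 6), 2000 mg/kg at day 8 (n = 6), vehicle at day 29 (n = 6), 200 mg/kg at day 29 (n = 6) and 2000 mg/kg at day 29 (n = 5). Each animal gave 1 array of the left liver lobe, and the labels call the arrays of a group biological replicates. The values are log2 signals centred on each transcript cluster's median over the 29 arrays, so they give differences between animals and no level of expression. Array medians ran from -0.023 to 0.029. The number of arrays limits the precision. Values below are log2 fold changes ± SE from a limma fit over all 29 animals, and adjusted p is the Benjamini-Hochberg value over 27342 transcript clusters. The rule for the largest rises or falls against vehicle took only genes with every treated animal on the same side of the vehicle mean.

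**Figure D1:**
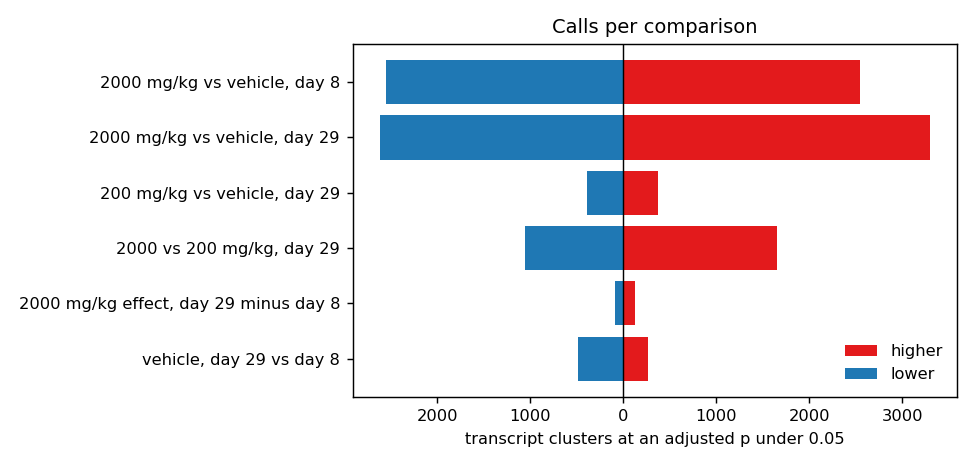
Transcript clusters that passed an adjusted p under 0.05 in each of 6 comparisons. Bars to the right count clusters that were higher in the first-named group (or had a more positive effect), and bars to the left count those that were lower. The bars at 2000 mg/kg hold 5096 clusters at day 8 and 5910 at day 29, against 761 at 200 mg/kg.

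The first comparison asked what 7 doses of 2000 mg/kg changed in the liver. Akr1b8, an aldo-keto reductase, was higher by 4.26 ± 0.22, a fold of 19.2. Abcc3, an efflux pump for conjugates, rose by 3.54 ± 0.13, Akr7a3, an aflatoxin aldehyde reductase, by 2.70 ± 0.13 and Nqo1, a quinone reductase, by 2.24 ± 0.11. Acot1, a cytosolic acyl-CoA thioesterase, showed the largest rise at 4.85 ± 0.34 (adjusted p = 3.33e-11). Dhrs7l1, a short-chain dehydrogenase/reductase family gene, showed the largest fall at -5.01 ± 0.31 (adjusted p = 1.89e-12). In all, 2548 clusters rose and 2548 fell, of which 107 and 106 changed by at least 2-fold.

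Of 22 measured NRF2 targets, genes of the electrophile response, 19 rose and 0 fell at day 8, and the counts were the same adjusted over the list alone. Their mean per animal was 0.86 ± 0.10 (SD, n = 6) after 2000 mg/kg and -0.38 ± 0.07 (SD, n = 6) in vehicle animals. Gclc and Gclm, the subunits of the enzyme that starts glutathione synthesis, rose by 0.81 ± 0.09 and 0.85 ± 0.08, Txnrd1 by 0.87 ± 0.08 and Hmox1, heme oxygenase, by 1.14 ± 0.18. Of 17 glutathione transferases 12 rose and 0 fell, over all genes and adjusted over the list alone, led by Gsta3 at 3.41 ± 0.17 and Gstp1 at 2.24 ± 0.15. Of 19 targets of the xenobiotic receptors CAR and PXR, 14 rose and 5 fell by either adjustment. Ces2c, a carboxylesterase, rose by 3.19 ± 0.14, Akr1b7 by 2.69 ± 0.24, Cyp2b2 by 1.91 ± 0.15 and Ugt2b1, a glucuronosyltransferase, by 1.85 ± 0.09. Cyp2b1 rose by 1.68 ± 0.17, whereas Cyp3a9 fell by 1.15 ± 0.27. These 3 lists passed camera with an estimated correlation at adjusted p = 2.15e-05, 0.000813 and 0.00209. Transcripts of close paralogs, such as Cyp2b1 with Cyp2b2 or Akr1b7 with Akr1b8, can share probes, so values within such a family are uncertain.

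Heat shock and proteasome genes rose together at day 8: 28 of 34 passed the test and 0 fell, with 29 rises adjusted over the list alone (adjusted p = 0.00335 with an estimated correlation). The small heat shock protein Hspb1 rose by 1.01 ± 0.16 and the proteasome subunit Psmd14 by 0.73 ± 0.14. In the list for endoplasmic reticulum and integrated stress, 12 of 31 genes rose and 2 fell, and adjusted over the list alone 14 rose. That list's call was lost with an estimated correlation (adjusted p = 0.117). Asns, asparagine synthetase, rose by 2.57 ± 0.19, and the serine synthesis enzymes Psat1 and Phgdh by 1.89 ± 0.20 and 1.15 ± 0.13. Among 33 PPAR-alpha targets 15 rose and 2 fell, with 16 rises adjusted over the list alone (adjusted p = 0.117 with an estimated correlation). Besides Acot1, the glycerol channel Aqp7 rose by 2.33 ± 0.23, Cpt1b by 2.07 ± 0.21 and the fatty acid transporter Cd36 by 1.90 ± 0.22. Cyp4a1, a classical PPAR-alpha target, had a value of 0.13 ± 0.07 (adjusted p = 0.217). The lipogenic genes Elovl6 and Me1 rose by 2.35 ± 0.20 and 1.84 ± 0.12, in a list of 24 with 7 rises and 8 falls, the same adjusted over the list alone (camera adjusted p = 0.59). Snx10, a sorting nexin, rose by 2.78 ± 0.20 and Coro6, a coronin, by 2.70 ± 0.12.

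Of 17 genes of the growth hormone and IGF axis 13 fell and 0 rose at day 8, and adjusted over the list alone 13 fell and 1 rose (adjusted p = 0.000626 with an estimated correlation). Socs2 and Cish, feedback inhibitors of cytokine signalling, fell by 2.06 ± 0.33 and 1.85 ± 0.36, Igfbp2 by 1.88 ± 0.17 and Egr1, an immediate early transcription factor, by 2.07 ± 0.31. Of 11 male-predominant liver genes 10 fell and 0 rose by either adjustment (adjusted p = 0.0173 with an estimated correlation), among them Mup5 at -3.06 ± 0.24, Stac3 at -2.43 ± 0.36, Ust5r at -1.25 ± 0.17 and Cyp2c11 at -1.05 ± 0.16. Periportal hepatocyte genes fell in 11 of 20 cases and rose in 1, with 12 falls adjusted over the list alone (adjusted p = 0.0338 with an estimated correlation). Sds, serine dehydratase, fell by 3.14 ± 0.31 and Gldc, of the glycine cleavage system, by 1.05 ± 0.14. Pericentral hepatocyte genes fell in 11 of 19 cases and rose in 4 by either adjustment (adjusted p = 0.117 with an estimated correlation). Of 14 female-predominant liver genes 4 rose and 4 fell, and 5 rose adjusted over the list alone (camera adjusted p = 0.895). Complement and coagulation genes fell in 30 of 34 cases by either adjustment (adjusted p = 0.0245 with an estimated correlation), with C1s at -1.45 ± 0.18 and Serpind1, heparin cofactor II, at -1.22 ± 0.10. In the urea cycle and amino acid breakdown list 19 of 30 genes fell by either adjustment, including Oat at -1.82 ± 0.16 and Prodh at -1.47 ± 0.15 (adjusted p = 0.0527 with an estimated correlation). Further falls were those of Car3 at -3.32 ± 0.30, Acnat2 at -3.16 ± 0.21, Aox3 at -2.80 ± 0.27, Nox4 at -2.72 ± 0.21 and Nrep at -2.17 ± 0.23. Ccnd1, cyclin D1, fell by 1.46 ± 0.14 in a cell cycle list of 40 with 2 rises and 3 falls, and 2 of each adjusted over the list alone (camera adjusted p = 0.522).

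Markers of other liver cells moved as well. Of 22 Kupffer cell and macrophage markers 16 fell and 1 rose at day 8 by either adjustment (adjusted p = 0.208 with an estimated correlation), among them Clec4f at -1.16 ± 0.24, Vsig4 at -1.11 ± 0.37, C1qb at -1.10 ± 0.25 and Adgre1 at -1.08 ± 0.28. The call of Vsig4 was lost without 2000 mg/kg replicate 3, 4 or 5 or vehicle replicate 2, 4 or 6, with adjusted p up to 0.0907. The mean of the macrophage markers was 0.58 ± 0.25 (SD, n = 6) in vehicle and -0.07 ± 0.20 (SD, n = 6) in treated animals. In vehicle animals of day 29 it was -0.15 ± 0.35 (SD, n = 6), near the treated animals of day 8. Stellate cell and fibrosis markers fell in 9 of 25 cases and rose in 1, with 11 falls adjusted over the list alone (adjusted p = 0.153 with an estimated correlation). Fn1, fibronectin, fell by 1.01 ± 0.07 and Pdgfrb by 0.57 ± 0.09. Endothelial markers fell in 4 of 13 cases by either adjustment (adjusted p = 0.263 with an estimated correlation). Markers of T, B and NK cells fell in 7 of 19 cases, and in 10 adjusted over the list alone (adjusted p = 0.161 with an estimated correlation). Erythrocyte markers fell in 3 of 10 cases, and in 6 adjusted over the list alone (adjusted p = 0.208 with an estimated correlation). Group means for day 8 vehicle, day 8 treated and day 29 vehicle animals were 0.19, -0.03 and -0.14 for endothelial markers. For erythrocyte markers they were 0.31, -0.02 and -0.02, for T, B and NK cell markers 0.15, -0.08 and 0.03, and for stellate markers 0.12, -0.10 and 0.26. For macrophage, endothelial and erythrocyte markers, a fall after PMCol cannot be told apart from a high level in day 8 vehicle animals. Among the genes given whatever their change, Cyp1a1, an aryl hydrocarbon receptor target, rose by 1.40 ± 0.38 (adjusted p = 0.00804). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had a value of 0.55 ± 0.34 (adjusted p = 0.301), Cdkn1a of -0.03 ± 0.20 (adjusted p = 0.959), Ttpa, the vitamin E transfer protein, of -0.10 ± 0.05 (adjusted p = 0.198), Vkorc1, the vitamin K epoxide reductase, of -0.06 ± 0.08 (adjusted p = 0.667) and Alb of 0.01 ± 0.04 (adjusted p = 0.902). Camera with its preset correlation called 26 of 38 lists and 8 with an estimated correlation. The total of 5096 among 27342 clusters became 3249 among the 7792 with a stored signal of 8 or more in all animals. That choice leaves out genes that fell below it.

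**Figure D2:**
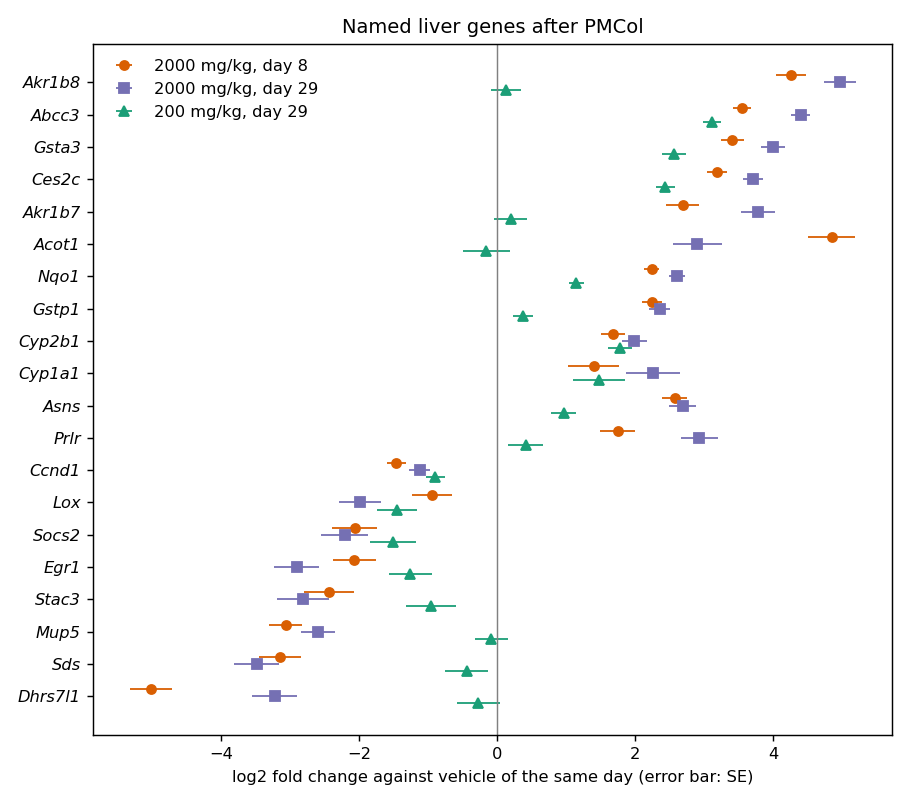
Log2 fold changes of 20 named genes against the vehicle group of the same day (horizontal axis, error bars SE), for 2000 mg/kg at day 8, 2000 mg/kg at day 29 and 200 mg/kg at day 29. Abcc3, Gsta3, Ces2c and Cyp2b1 lie to the right at both doses, whereas Akr1b8 is at 0.13 after 200 mg/kg and at 4.97 after 2000 mg/kg at day 29.

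After 28 doses of 2000 mg/kg the same comparison gave 3298 rises and 2612 falls, of which 142 and 129 reached 2-fold. Akr1b8 rose by 4.97 ± 0.23, Abcc3 by 4.40 ± 0.14, Gsta3 by 4.00 ± 0.18, Akr1b7 by 3.78 ± 0.25 and Ces2c by 3.71 ± 0.15. Prlr, the prolactin receptor, which is female-predominant in rat liver, rose by 2.93 ± 0.26. The falls were led by Sds at -3.48 ± 0.32, Dhrs7l1 at -3.22 ± 0.32, Egr1 at -2.91 ± 0.33, Stac3 at -2.81 ± 0.38 and Mup5 at -2.60 ± 0.25. The immediate early receptor gene Nr4a1 had a value of -2.59 ± 0.40 and Scd, stearoyl-CoA desaturase, of -2.41 ± 0.34, both past the threshold.

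NRF2 targets rose in 19 of 22 cases at day 29 by either adjustment (adjusted p = 0.000108 with an estimated correlation), with Nqo1 at 2.61 ± 0.11, Gclc at 0.94 ± 0.09, Hmox1 at 1.29 ± 0.19 and Txnrd1 at 0.77 ± 0.08. Glutathione transferases rose in 10 of 17 cases and fell in 1, with 11 rises and 2 falls adjusted over the list alone (adjusted p = 0.00745 with an estimated correlation). Gstp1 rose by 2.36 ± 0.15, Mgst2 by 1.09 ± 0.13 and Gstt1 by 1.00 ± 0.08. CAR and PXR targets rose in 13 of 19 cases and fell in 1, with 3 falls adjusted over the list alone (adjusted p = 0.00661 with an estimated correlation), Cyp2b2 by 2.24 ± 0.16 and Cyp2b1 by 1.99 ± 0.18. Heat shock and proteasome genes rose in 23 of 34 cases, and in 27 adjusted over the list alone (adjusted p = 0.0231 with an estimated correlation). Asns rose by 2.69 ± 0.19 in a stress list of 31 with 14 rises and 5 falls, and 16 and 6 adjusted over the list alone (adjusted p = 0.376 with an estimated correlation). In cholesterol synthesis 10 of 20 genes rose and 2 fell, and 11 rose adjusted over the list alone (adjusted p = 0.377 with an estimated correlation). Without vehicle replicates 1 and 2 together these 2 list calls were lost (camera adjusted p = 0.111 and 0.0657). Among 33 PPAR-alpha targets 12 rose and 7 fell by either adjustment (camera adjusted p = 0.143). The list passed camera at the preset correlation without vehicle replicate 2 (adjusted p = 0.0308), but not with an estimated correlation over all animals. The synthesis enzymes Dhcr7 and Sqle rose by 0.80 ± 0.12 and 0.70 ± 0.19, while Insig1, a sterol-responsive regulator, fell by 1.33 ± 0.18.

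Growth hormone and IGF axis genes fell in 11 of 17 cases and rose in 1 at day 29, with 12 falls adjusted over the list alone (adjusted p = 0.00184 with an estimated correlation). Socs2 fell by 2.21 ± 0.34, Igfbp1 by 2.14 ± 0.26 and Igfbp3 by 1.53 ± 0.12. Male-predominant genes fell in 7 of 11 cases, and in 8 adjusted over the list alone (adjusted p = 0.0495 with an estimated correlation). Cyp2c11 fell by 0.68 ± 0.17. Of 14 female-predominant genes, with Prlr and Akr1b7 among them, 5 rose and 2 fell, and 6 rose adjusted over the list alone (camera adjusted p = 0.0414, and adjusted p = 0.371 with an estimated correlation). The camera call was lost without vehicle replicate 1 (adjusted p = 0.135), without 2000 mg/kg replicate 1 or 5 (0.0713 and 0.0606) and without vehicle replicates 1 and 2 together (0.11). Pericentral genes fell in 6 of 19 cases and rose in 3, with 8 falls adjusted over the list alone (adjusted p = 0.241 with an estimated correlation). Periportal genes fell in 10 of 20 cases and rose in 1, with 11 falls adjusted over the list alone (adjusted p = 0.0495 with an estimated correlation). The fall of urea cycle and amino acid breakdown genes, 19 of 30 and 20 adjusted over the list alone with 1 rise, and of complement and coagulation genes, 24 of 34 and 28 adjusted over the list alone, lost the call with an estimated correlation (adjusted p = 0.0572 and 0.0941). Stellate cell and fibrosis markers fell in 20 of 25 cases and rose in 0, with 21 falls adjusted over the list alone (adjusted p = 0.00745 with an estimated correlation). Lox, a collagen crosslinking enzyme, fell by 1.99 ± 0.30, Lrat, which stores retinol as esters, by 1.40 ± 0.14 and Pdgfrb by 0.97 ± 0.10. Their mean per animal was -0.34 ± 0.06 (SD, n = 5) after 2000 mg/kg and 0.26 ± 0.16 (SD, n = 6) in vehicle animals. Of 22 macrophage markers 1 rose by either adjustment, Cd14 at 0.76 ± 0.14, and 0 fell (camera adjusted p = 0.878). Endothelial markers rose in 1 of 13 cases and fell in 2 by either adjustment (camera adjusted p = 0.802). In a list of 23 immediate early genes put together after the values were seen, 12 fell, and 17 adjusted over the list alone. The immediate early mean was -0.45 ± 0.15 (SD, n = 5) in treated and 0.42 ± 0.19 (SD, n = 6) in vehicle animals.

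Ttpa fell by 0.18 ± 0.06 at day 29 (adjusted p = 0.0187), a call lost without 2000 mg/kg replicate 4 or 5 or vehicle replicate 6, with adjusted p up to 0.0635. Ggcx, the vitamin K-dependent carboxylase, and Vkorc1l1 rose by 0.59 ± 0.07 and 0.46 ± 0.07. The list of vitamin E and vitamin K handling held 2 rises and 8 falls among 19 genes, and 9 falls adjusted over the list alone (adjusted p = 0.287 with an estimated correlation). Cyp1a1 rose by 2.26 ± 0.39 and Cyp3a9 fell by 1.25 ± 0.28. Cyp7a1, Cyp4a1, Cdkn1a, Vkorc1 and Alb had values of -0.49 ± 0.35, -0.03 ± 0.07, -0.25 ± 0.21, 0.08 ± 0.08 and -0.02 ± 0.04, none past the limma threshold (adjusted p of 0.369 or more). Camera called 24 of 38 lists with its preset correlation and 8 with an estimated one. With the immediate early mean as a covariate, which itself differed between these groups, the total of 5910 became 1764. Among the 7792 clusters with a stored signal of 8 or more, 3560 passed.

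**Figure D3:**
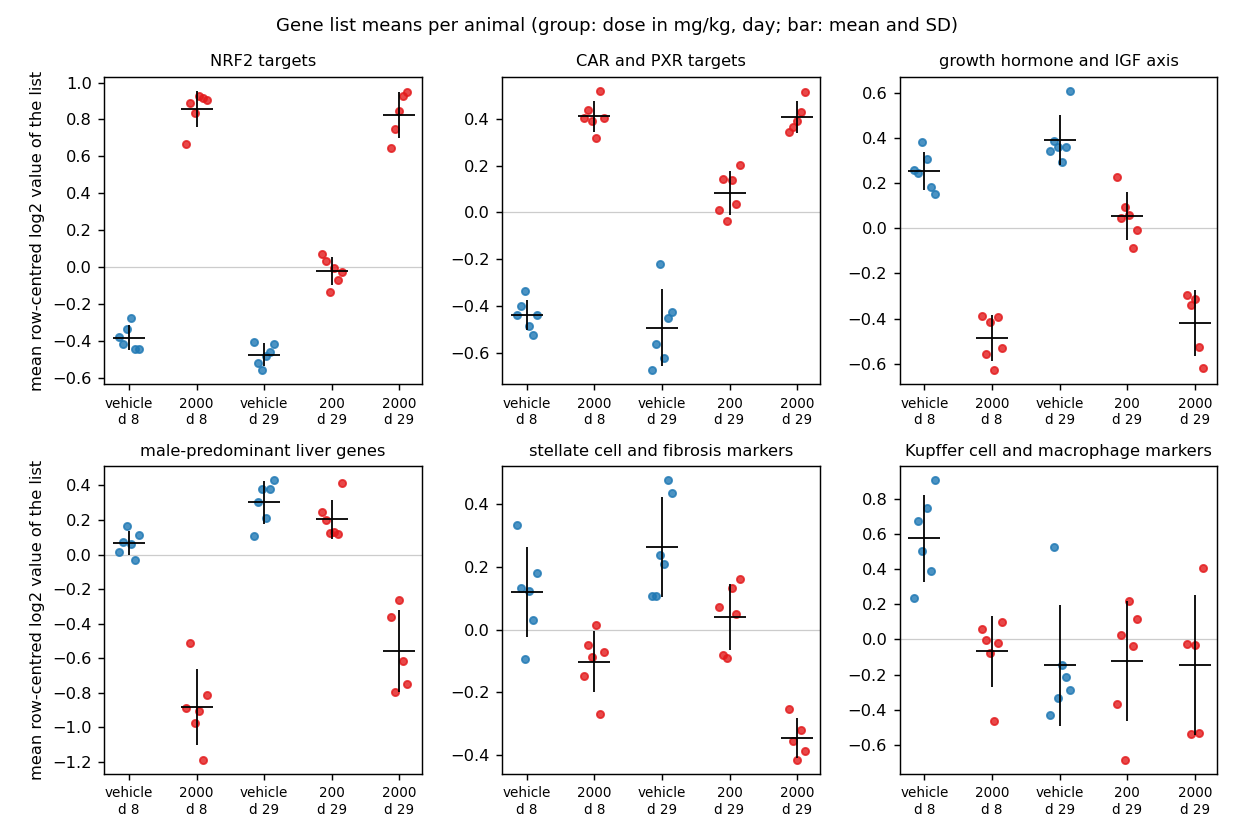
Mean row-centred log2 value of 6 gene lists in each animal (points, vehicle in blue and PMCol in red), by dose in mg/kg and day, with the group mean and SD as black bars. NRF2 targets lie at -0.02 after 200 mg/kg, between the day 29 vehicle mean of -0.47 and the 2000 mg/kg mean of 0.82, and 1 vehicle animal of day 29 stands at 0.53 for macrophage markers.

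At 200 mg/kg for 28 doses, 374 clusters rose and 387 fell against vehicle, of which 24 and 14 reached 2-fold. Abcc3 rose by 3.11 ± 0.13, Gsta3 by 2.56 ± 0.17, Ces2c by 2.43 ± 0.14, Ces2e, a further carboxylesterase, by 1.74 ± 0.12, Cyp2b2 by 1.84 ± 0.15 and Cyp2b1 by 1.78 ± 0.17. Fkbp5, a glucocorticoid-induced chaperone partner, rose 2.83-fold, Cryl1 by 1.49 ± 0.16 and Akr7a3 by 1.48 ± 0.13. CAR and PXR targets rose in 8 of 19 cases, and 12 rose and 1 fell adjusted over the list alone (adjusted p = 0.000306 with an estimated correlation). NRF2 targets rose in 9 of 22 cases, and 12 rose and 1 fell adjusted over the list alone (adjusted p = 0.000975 with an estimated correlation), with Nqo1 at 1.15 ± 0.11. Gclm, Gstp1, Hmox1 and Txnrd1 had values of 0.14 ± 0.08, 0.38 ± 0.15, 0.52 ± 0.18 and 0.26 ± 0.08 that did not pass (adjusted p of 0.0563 or more). Glutathione transferases rose in 6 of 17 cases, and in 7 adjusted over the list alone (adjusted p = 0.0093 with an estimated correlation).

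The falls at 200 mg/kg were led by Socs2 at -1.51 ± 0.33, Lox at -1.45 ± 0.29, Cish at -1.37 ± 0.36, Dusp6, a MAP kinase phosphatase, at -1.27 ± 0.20 and Egr1 at -1.26 ± 0.31. Slc25a30, Slc25a25, Sik1, Wsb1 and Aox3 followed at -1.11 ± 0.27, -1.08 ± 0.22, -1.05 ± 0.24, -1.01 ± 0.16 and -0.98 ± 0.27, and Ccnd1 fell by 0.90 ± 0.14. Growth hormone and IGF axis genes fell in 4 of 17 cases, and 11 fell and 1 rose adjusted over the list alone (adjusted p = 0.0188 with an estimated correlation). In the p53 and DNA damage list 3 of 20 genes rose, and 7 rose and 1 fell adjusted over the list alone (adjusted p = 0.0521 with an estimated correlation), with Plk3 at 1.04 ± 0.16, Plk2 at 0.54 ± 0.10 and Cdkn1a, which did not pass, at 0.61 ± 0.20 (adjusted p = 0.106). The 11 male-predominant genes had a median of 0.01 (camera adjusted p = 0.669). Of 14 female-predominant genes 0 rose and 2 fell by either adjustment (camera adjusted p = 0.134). That list passed camera at the preset correlation without vehicle replicate 1 (adjusted p = 0.0307), but not with an estimated correlation over all animals. Of 33 PPAR-alpha targets 1 rose and 1 fell, and 7 fell adjusted over the list alone, with a median of -0.06 (camera adjusted p = 0.0537, and adjusted p = 0.764 with an estimated correlation). That list passed camera without vehicle replicate 1, 5 or 6 (adjusted p = 0.00666, 0.0163 and 0.0167) or 200 mg/kg replicate 2, 4 or 6 (0.0215, 0.0296 and 0.0447). Of 22 macrophage markers 1 rose by either adjustment, Cd14 at 0.79 ± 0.13 (camera adjusted p = 0.994). Stellate cell and fibrosis markers fell in 2 of 25 cases, and in 8 adjusted over the list alone (adjusted p = 0.08 with an estimated correlation). Of 13 endothelial markers 0 passed and 4 rose adjusted over the list alone (adjusted p = 0.43 with an estimated correlation). Pericentral genes fell in 4 of 19 cases and rose in 2, with 6 falls adjusted over the list alone (adjusted p = 0.284 with an estimated correlation), and complement and coagulation genes fell in 2 of 34 cases by either adjustment (adjusted p = 0.409 with an estimated correlation). Of 34 heat shock and proteasome genes 0 passed by either adjustment (camera adjusted p = 0.105). At the preset correlation the list passed camera without vehicle replicate 3 or 6 (adjusted p = 0.0198 and 0.0431) or 200 mg/kg replicate 3, 4 or 5 (0.0239, 0.0354 and 0.0351). It did not pass with an estimated correlation over all animals. Several calls were lost when 1 animal was left out, while the values moved by less than 1.5 times. That of Cish was lost without 200 mg/kg replicate 2, 4, 5 or 6 or vehicle replicate 1, 2 or 6, with values of -1.36 to -1.09 and adjusted p up to 0.0988. That of Egr1 was lost without 200 mg/kg replicate 5 or 6 or vehicle replicate 5 or 6, with values of -1.16 to -1.12 and adjusted p up to 0.0758, and that of Slc25a30 without 200 mg/kg replicate 3 or 5, with values of -0.96 and -0.98 and adjusted p up to 0.0629. That of Aox3 was lost without 200 mg/kg replicate 2, 4, 5 or 6 or vehicle replicate 2, 3, 5 or 6, with values of -1.01 to -0.88 and adjusted p up to 0.12. Cyp1a1 rose by 1.48 ± 0.38 (adjusted p = 0.0275), a call lost without 200 mg/kg replicate 4, 5 or 6 or vehicle replicate 5 or 6, with values of 1.18 to 1.51 and adjusted p up to 0.0818. Gclc rose by 0.34 ± 0.09 (adjusted p = 0.035), a call lost without 200 mg/kg replicate 2, 4, 5 or 6 or vehicle replicate 1, 3 or 6, with values of 0.28 to 0.34 and adjusted p up to 0.0984. The remaining genes given whatever their change, Cyp3a9, Cyp2c11, Cyp4a1, Cyp7a1 and Ttpa, had values of -0.76, 0.04, -0.11, -0.36 and -0.02, and Vkorc1 and Alb lay closer to 0 (limma adjusted p of 0.141 or more). Without 200 mg/kg replicate 1 there were 470 rises and 632 falls, and without vehicle replicate 1 there were 305 rises and 447 falls, so the balance of 374 and 387 moved with single animals. The total of 761 was 436 without 200 mg/kg replicate 5, 451 without 200 mg/kg replicate 6, 340 in a fit of these 12 animals alone and 196 with the immediate early mean as a covariate. Camera called 13 of 38 lists with its preset correlation and 4 with an estimated one.

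The doses were compared directly at day 29. Of 2704 clusters that differed, 1653 were higher and 1051 lower at 2000 mg/kg. Akr1b8 was higher by 4.84 ± 0.23, Akr1b7 by 3.59 ± 0.25, Acot1 by 3.06 ± 0.36, Prlr by 2.52 ± 0.26 and Derl3, a factor of endoplasmic reticulum protein degradation, by 1.98 ± 0.14. At 200 mg/kg Akr1b8, Akr1b7 and Acot1 had values against vehicle of 0.13 ± 0.22, 0.20 ± 0.24 and -0.15 ± 0.34. The falls were led by Sds at -3.04 ± 0.32, Dhrs7l1 at -2.95 ± 0.32, Mup5 at -2.51 ± 0.25, Scd at -2.28 ± 0.34 and Slc13a5, a citrate transporter, at -1.97 ± 0.22. Slc13a5 rose by 0.88 ± 0.21 against vehicle at 200 mg/kg (adjusted p = 0.0163) and fell by 1.09 ± 0.22 at 2000 mg/kg (adjusted p = 0.000438). For Cyp2b1 the doses differed by 0.21 ± 0.18 (95% interval -0.17 to 0.59, adjusted p = 0.554). NRF2 targets were higher at 2000 mg/kg in 19 of 22 cases by either adjustment (adjusted p = 8.98e-05 with an estimated correlation). Male-predominant genes were lower in 8 of 11 cases, stellate markers in 15 of 25 and periportal genes in 10 of 20 with 1 higher, and heat shock and proteasome genes were higher in 21 of 34. Adjusted over the list alone these counts were 9, 16, 11 and 24 (adjusted p = 0.0137 in each case with an estimated correlation). The total was 1755 without 2000 mg/kg replicate 5 and 1503 with the immediate early mean as a covariate.

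Of 761 calls at 200 mg/kg, 641 were also called in the same direction at 2000 mg/kg on day 29, and 2 in the opposite one. Independent lists of these sizes would share 82.1. The comparisons used the same vehicle animals. In simulations without effects, both dose groups and a shared vehicle group were drawn from the pooled residuals of the 29 arrays. They shared 0 calls on average, which leaves open what shared vehicle animals add where both doses have effects. Across clusters, which are not independent replicates, the fold changes of the doses correlated at r = 0.72, against a simulated mean of 0.46. Most simulated values lay between -0.01 and 0.77. The observed r was therefore inside the spread simulated without effects. The covariance was 0.0264, against 0.0033 when simulated. The difference of 0.0231 estimates the covariance that shared vehicle animals do not give, if the real ones vary as the pooled residuals do. With the vehicle animals split into sets of 3, r averaged 0.53 (range 0.40 to 0.61 over 20 splits) and the shared calls had a median of 270, where independent lists of those sizes would share a median of 31.8. The overlap was 384 without 200 mg/kg replicate 5, 385 without replicate 6 and 137 with the immediate early mean as a covariate. Between day 8 and day 29 at 2000 mg/kg, which share no animals, 2966 calls had the same direction, 26 the opposite one and independent lists would share 551. Their fold changes correlated at r = 0.74 across clusters. That overlap was 1375 with the immediate early mean as a covariate.

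The effect of 2000 mg/kg was then compared between day 29 and day 8 by an interaction term, which 212 clusters passed, 129 with a more positive and 83 with a more negative effect at day 29. Ces2e rose by 1.41 ± 0.12 at day 8 and 2.62 ± 0.12 at day 29, a difference of 1.21 ± 0.17. Vehicle animals of day 29 had Ces2e lower than those of day 8 by about as much. Treated animals therefore lay at about the same level of Ces2e on both days. Dbp, a clock-controlled transcription factor, differed by 1.21 ± 0.27, Nat8 by 1.16 ± 0.20, Sema3c by 1.07 ± 0.22 and Mmd by 1.03 ± 0.20. Nat8 fell by 0.75 ± 0.14 at day 8 and rose by 0.41 ± 0.14 at day 29. Igfbp1 had a value of 0.05 ± 0.25 at day 8 and fell by 2.14 ± 0.26 at day 29, a difference of -2.18 ± 0.37. Gadd45b, Noct, Jun and Apold1 differed by -2.16 ± 0.42, -1.94 ± 0.46, -1.76 ± 0.43 and -1.47 ± 0.31. Of the 38 lists fixed in advance, 0 passed camera with an estimated correlation for this difference, 3 had an unadjusted p under 0.05 there and 2 passed fry. Lists that passed with the preset correlation included interferon response genes (4 of 33 more positive and 17 adjusted over the list alone, adjusted p = 0.441 with an estimated correlation), macrophage markers (0 of 22 more positive and 14 adjusted over the list alone, adjusted p = 0.732 with an estimated correlation) and stellate markers (3 of 25 more negative and 13 adjusted over the list alone, adjusted p = 0.162 with an estimated correlation). The count of 212 was 563 without vehicle day 29 replicate 2, and 137, 99 and 123 without vehicle day 29 replicates 3, 5 and 6. It was 96 and 138 without vehicle day 8 replicates 2 and 4, 76 and 114 without 2000 mg/kg day 8 replicates 1 and 6, and 114 and 78 without 2000 mg/kg day 29 replicates 1 and 5. Without vehicle day 29 replicate 4 there were 100 more positive and 51 more negative effects, without 2000 mg/kg day 29 replicate 3 there were 109 and 55, and without replicate 4 of that group 84 and 66. The count was 102 after quantile normalization, 673 with array quality weights, 620 without vehicle day 29 replicates 1 and 2, 28 with the macrophage mean and 4 with the immediate early mean as a covariate. The call of Apold1 was lost without 2000 mg/kg day 8 replicate 1 (adjusted p = 0.0506). That of Dbp was lost without vehicle day 8 replicate 2 or 4, vehicle day 29 replicate 4 or 6, 2000 mg/kg day 8 replicate 1, 4 or 5 or 2000 mg/kg day 29 replicate 1, 3 or 5, with adjusted p up to 0.0682. That of Noct was lost without vehicle day 8 replicate 1, 2 or 4, vehicle day 29 replicate 3, 4, 5 or 6, 2000 mg/kg day 8 replicate 1, 4 or 5 or 2000 mg/kg day 29 replicate 2, 3, 4 or 5, with adjusted p up to 0.0702. That of Jun was lost without any 1 animal of these groups other than vehicle day 8 replicate 3, vehicle day 29 replicate 2 and 2000 mg/kg day 8 replicate 2, with adjusted p up to 0.0914.

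Vehicle animals of day 29 differed from those of day 8 in 746 clusters, 263 higher and 483 lower. Vsig4, a macrophage marker, was lower by 1.70 ± 0.37, Cybb, a phagocyte oxidase subunit, by 1.32 ± 0.29, C1qb by 1.26 ± 0.25 and Alox15 by 1.38 ± 0.19. Ces2e was lower by 1.22 ± 0.12. Of 22 macrophage markers 14 were lower, and 17 lower and 1 higher adjusted over the list alone (adjusted p = 0.38 with an estimated correlation). Endothelial markers were lower in 5 of 13 cases, and in 9 adjusted over the list alone (adjusted p = 0.38 with an estimated correlation), while stellate markers were higher in 2 of 25 and in 5 adjusted over the list alone (adjusted p = 0.677 with an estimated correlation). Erythrocyte markers were lower in 2 of 10 cases, and 5 were lower and 1 higher adjusted over the list alone (adjusted p = 0.536 with an estimated correlation). Stac3 was higher by 1.78 ± 0.36, Lrtm2 by 1.31 ± 0.21, Il1rn, the interleukin-1 receptor antagonist, by 1.05 ± 0.21, Hamp, hepcidin, by 0.95 ± 0.25 and Znf57l by 0.90 ± 0.16. The call of Hamp was lost without vehicle day 29 replicate 1, 3, 4, 5 or 6 or vehicle day 8 replicate 1, 2, 5 or 6, with adjusted p up to 0.104. The total was 2141 without vehicle day 29 replicate 2, and 398, 451, 254 and 254 without vehicle day 29 replicates 1, 4, 5 and 6. Without vehicle day 29 replicate 3, 157 were higher and 351 lower. The total was 297, 298 and 314 without vehicle day 8 replicates 2, 4 and 6, 136 in a fit of these 12 animals alone, 1773 with array quality weights, 1374 without vehicle day 29 replicates 1 and 2, 14 with the macrophage mean and 30 with the immediate early mean as a covariate.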

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

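The tests of the patterns weighed here were chosen after the results had been seen. The splits of the animals had been planned before. Each of the 6 comparisons was set against 100 splits of the same animals, the real one included. In each case 1 split, the real one, gave as many calls. The splits drawn were a part of those possible, so they argue against a chance arrangement of the animals without excluding it. For the difference between days the splits exchanged day labels within treated and within vehicle animals. That also removes a day effect common to both, so these splits cannot decide on chance for the interaction. The real counts and the highest of the other splits were 5096 and 1081 for 2000 mg/kg at day 8, 5910 and 5455 for 2000 mg/kg at day 29, 761 and 375 for 200 mg/kg, 2704 and 10 for the doses, 212 and 32 for the difference between days, and 746 and 10 for the vehicle groups. The split with 5455 calls only moved vehicle replicate 2 to the side of the 5 treated animals.

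The first pattern is vehicle day 29 replicate 2, whose macrophage mean of 0.53 lay in the range of the day 8 vehicle animals. It was placed over 2124 clusters outside the macrophage list that separated day 8 from the other day 29 vehicle animals. Its median position was 0.0902, where 0 is the day 8 mean and 1 the day 29 mean. The other day 29 vehicle animals ran from 0.79 to 1.10, each over 247 to 500 clusters chosen without that animal. Replicate 2 stayed in that choice and in their day 29 mean, so their positions are not directly comparable with that of replicate 2. Over 1009 clusters with a low correlation to the macrophage mean among treated animals, the position of replicate 2 was 0.14. That filter rests on few animals and can keep clusters that follow macrophages. With the macrophage mean as a covariate 14 clusters passed between the vehicle groups, against 746 without it. That drop cannot decide either, because the macrophage mean itself differed between these groups. The immediate early mean as a covariate gave a like drop, to 30. A difference in macrophage content alone is therefore not settled by these values. An exchange of 2 arrays between the groups is argued against, since the highest day 8 vehicle animal was at 0.34. For a day 8 vehicle array under a day 29 label the values go both ways. Among the 50 clusters that separated the vehicle groups most, 9 lay over a position of 0.75 in this animal. At most 2 did in any day 8 vehicle animal, and 13 to 40 in the other day 29 vehicle animals. Its median position over these clusters was 0.23, inside the day 8 range of -0.03 to 0.28. The other day 29 vehicle animals had medians of 0.56 to 1.04. The condition on these clusters was added after the results had been seen, and before that the values had met the prediction for this explanation. Of the 38 lists fixed in advance, the animal's mean lay outside the day 8 range but inside that of the other day 29 animals for 10. The other way round held for 10. A day 8 array under a day 29 label, a difference in macrophage content and another unrecorded difference between animals cannot be told apart.

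The second pattern is the lower macrophage mean of day 29 vehicle animals, a difference of -0.72 on the log2 scale (6 against 6), for a list that lost its call with an estimated correlation (adjusted p = 0.38). No single animal set it, since the difference nearest to 0 with 1 animal left out was -0.66. Whether every cell type other than hepatocytes made up a smaller share is not settled by these values. Macrophage minus the mean of endothelial and stellate markers differed by -0.63 (exact permutation p = 0.00649, two-sided), with endothelial markers at -0.33 and stellate markers at 0.14. Macrophage minus the mean of 6 other cell types differed by -0.60 (exact permutation p = 0.00866, two-sided). Among these, erythrocyte markers were at -0.33, lymphocyte markers at -0.12, bile duct markers at -0.06 and neutrophil markers at -0.02. The macrophage list was picked because it fell. An offset before the log would make folds of dim genes smaller, so unequal shifts do not show unequal shares. With the immediate early mean as a covariate the difference was -0.44 ± 0.23 (SE), between the bounds set for either answer, so variation that moves with immediate early genes cannot be told apart from it. Age of the animals and length of dosing with vehicle remain open and were not tested.

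The third pattern is the lower immediate early mean after 2000 mg/kg at day 29, a difference of -0.87, against -0.20 at day 8, over a list put together after the values were seen, so no p is given for either difference. After 200 mg/kg the mean was -0.04 ± 0.44 (SD, n = 6), with animals from -0.51 to 0.66, against 0.42 in day 29 vehicle animals. With 1 animal left out the difference after 2000 mg/kg at day 29 that was nearest to 0 was -0.81. Against day 8 vehicle animals, the vehicle animals of day 29 differed by 0.40 and the treated animals of day 29 by -0.47, and because the choice of genes had seen these animals, a raised level in day 29 vehicle animals cannot be told apart from a lowered level in treated ones. Handling at death and an effect of PMCol remain open as well, and the order of killing was not among the labels used here.

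An animal stood apart from the rest of its group in 51 of 815 group values tested, 6.26%, where chance gives about 1 in 20; vehicle day 29 replicate 1 was that animal in 12 cases. The values below are the gap to the nearest animal over the range of the group. For vehicle day 29 replicate 1 they were 0.774 for vitamin E and vitamin K handling, 0.629 for complement and coagulation, 0.654 for heme and iron, 0.664 for neutrophil markers, 0.725 for markers of other tissues, 0.635 for Akr1b8, 0.657 for Psmd14, 0.721 for Serpind1, 0.662 for Vkorc1l1, 0.660 for Ggcx, 0.799 for the SD of the array and 0.782 for its median. For vehicle day 29 replicate 2 they were 0.738 for glutathione transferases, 0.703 for macrophage markers, 0.748 for Clec4f, 0.633 for Vsig4, 0.694 for C1qb and 0.736 for Adgre1. Other vehicle day 29 animals gave 0.695 for the growth hormone axis, 0.633 for ribosomal proteins and 0.679 for bile duct markers. Vehicle day 8 animals gave 0.627 for glutathione synthesis, 0.648 for lymphocyte markers, 0.706 for erythrocyte markers and 0.671 for Cyp2b1. Animals given 2000 mg/kg for 7 days gave 0.645 for NRF2 targets, 0.691 for macrophage markers, 0.641 for Akr7a3, 0.891 for Nox4, 0.649 for Txnrd1, 0.755 for Cyp2b2, 0.844 for Ust5r, 0.678 for Clec4f, 0.639 for Scd and 0.694 for Igfbp3. Those given it for 28 days gave 0.729 for glucuronosyl- and sulfotransferases, 0.894 for periportal genes, 0.781 for Txnrd1, 0.743 for Aqp7, 0.745 for Plk2, 0.716 for Fkbp5 and 0.745 for Slc25a30. Animals given 200 mg/kg gave 0.746 for Akr7a3, 0.664 for Asns, 0.666 for Sds, 0.776 for Gldc, 0.657 for Clec4f, 0.681 for Sema3c, 0.688 for Lrtm2, 0.756 for Znf57l and 0.705 for Epcam.

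The effect of 2000 mg/kg differed between the days by the interaction test for 14 of the genes named. Ces2e, Dbp, Nat8, Sema3c, Mmd, Igfbp1, Gadd45b, Noct, Jun and Apold1 were named as the largest calls of this same test. For those genes passing was fixed by the choice. The difference, day 29 minus day 8, was 0.86 for Abcc3, -0.87 for Lrat, -2.18 for Igfbp1, -1.04 for Igfbp3, 1.21 for Ces2e, 1.21 for Dbp, 1.16 for Nat8, 1.07 for Sema3c, 1.03 for Mmd, -2.16 for Gadd45b, -1.94 for Noct, -1.76 for Jun, -1.47 for Apold1 and 0.81 for Cxcl11.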

How the results depend on the processing

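The alternatives with clusters of a stored signal of 8 or more, without vehicle day 29 replicates 1 and 2 together and with a covariate were chosen after seeing the data. The planned filters on dim clusters and the pseudocounts were not run, because the values carry no level and were already on the log2 scale. Signal over background cannot be read from centred values, so the limit it sets is not known. Counts within 1.5 times the first value are not listed. With an adjusted p under 0.01 the counts were 3244 for 2000 mg/kg at day 8, 3754 for 2000 mg/kg at day 29, 277 for 200 mg/kg, 1364 for the doses, 28 for the difference between days and 77 for the vehicle groups, and with an absolute log2 fold change of 1 or more they were 213, 271, 38, 106, 36 and 20; both follow from the stricter threshold. Over clusters with a stored signal of 8 or more 3249 and 3560 passed for 2000 mg/kg at day 8 and day 29, with 7792 clusters tested in place of 27342. With the immediate early mean as a covariate, 1764 passed for 2000 mg/kg at day 29, 196 for 200 mg/kg, 1503 for the doses, 4 for the difference between days and 30 for the vehicle groups, and the overlaps were 137 between doses and 1375 between days; that mean differed between the groups. With the macrophage mean, which differed between the vehicle groups as well, 28 passed for the difference between days and 14 for the vehicle groups. In fits of the compared groups alone 340 passed for 200 mg/kg and 136 for the vehicle groups. For the difference between days quantile normalization gave 102, array quality weights 673 and leaving out vehicle day 29 replicates 1 and 2 gave 620; for the vehicle groups the weights gave 1773 and leaving out those animals 1374. The cause was not tested for these. With an estimated correlation camera called 8, 8 and 4 lists for 2000 mg/kg at day 8 and day 29 and for 200 mg/kg, against 26, 24 and 13.

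Leaving out 1 animal at a time gave 4400 to 4802 calls for 2000 mg/kg at day 8, 4791 to 6313 at day 29, 436 to 1102 for 200 mg/kg, 1755 to 2813 for the doses, 76 to 563 for the difference between days and 254 to 2141 for the vehicle groups. The overlap ran from 384 to 906 between doses and from 2660 to 3072 between days, and the correlation of the doses from 0.68 to 0.75. Called lists ran from 26 to 27, 21 to 26 and 10 to 15. With the replicate number as a block the counts were 5008, 5964, 780, 2736, 224 and 799, and 113 of 114 list results and 361 of 367 gene results kept their side of the threshold. The numbers did not pair the animals: 3 of 29 arrays correlated best with their own number, and r of same-numbered animals ran from -0.28 to 0.30. Of 4378 gene results with 1 animal left out 4087 kept their side of the threshold and 0 reversed. Of 367 gene results 358 kept it after quantile normalization, 334 in fits of the compared groups alone, 316 with the macrophage mean and 265 with the immediate early mean as a covariate; of 114 list results 71 kept it with an estimated correlation and 96 with fry. With the macrophage mean as a covariate Vsig4 and Cd4 at day 8 of 2000 mg/kg turned to 0.27 and 0.0653 (adjusted p = 0.0803 and 0.712), and with the immediate early mean Atf3 at day 29 turned to 1.34 (adjusted p = 0.0885). Vsig4 and Atf3 are members of the list whose mean was the covariate, so the fit removes part of their own change; for Cd4 the cause was not tested.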

Other observations

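Carboxylesterases, a list put together after the values were seen, rose in 4 of 9 cases at both days of 2000 mg/kg and in 3 of 9 at 200 mg/kg. Of 31 amino acid transporters and synthetases, a list made in the same way, 20 rose and 2 fell at day 8 and 17 rose and 2 fell at day 29 of 2000 mg/kg. Their day 29 mean was -0.04 ± 0.04 (SD, n = 6) after 200 mg/kg, -0.12 ± 0.05 (SD, n = 6) in vehicle animals and 0.25 ± 0.10 (SD, n = 5) after 2000 mg/kg. No set test is given for these lists, since the values prompted them. Among lists fixed before the data were examined, acute phase genes fell in 16 of 26 cases and rose in 1 at day 8 of 2000 mg/kg, with 16 falls and 2 rises adjusted over the list alone, and genes of the methionine cycle fell in 14 of 25 and rose in 2, with 17 falls adjusted over the list alone (adjusted p = 0.117 for each with an estimated correlation). At day 29 these lists had 12 falls and 2 rises, and 10 falls and 3 rises, with 14 falls in the first and 11 falls and 4 rises in the second adjusted over the list alone (adjusted p = 0.241 and 0.377 with an estimated correlation). In the p53 and DNA damage list 8 of 20 genes rose at day 8 of 2000 mg/kg, and 9 adjusted over the list alone (adjusted p = 0.0726 with an estimated correlation). At day 29 the p53 list had 8 rises and 2 falls by either adjustment (camera adjusted p = 0.108). It passed camera at the preset correlation without 2000 mg/kg replicate 3 (adjusted p = 0.0415), but not with an estimated correlation over all animals. Vitamin E and vitamin K handling genes fell in 10 of 19 cases and rose in 2 at day 8 of 2000 mg/kg, with 11 falls adjusted over the list alone (adjusted p = 0.117 with an estimated correlation). Ribosomal protein genes rose in 17 of 44 cases at day 8 and 21 of 44 at day 29, and in 21 and 23 adjusted over the list alone, with medians of 0.13 and 0.15 (adjusted p = 0.0768 and 0.127 with an estimated correlation). Epcam, a marker of bile duct and progenitor cells, rose by 0.82 ± 0.11 at day 8 and 0.88 ± 0.12 at day 29 of 2000 mg/kg. The clock gene Npas2 fell by 1.58 ± 0.12 and 1.56 ± 0.13.

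How much of the 2000 mg/kg effect was present at 200 mg/kg was computed for 2 lists of induced genes after the values were seen. At day 29 the mean of the CAR and PXR targets at 200 mg/kg reached 63.8% of its change at 2000 mg/kg, and the mean of the NRF2 targets 34.9%. By the medians over genes the shares were 43.2% and 32.1%, so the size of the gap depends on the use of means. No test is given, since the values prompted the comparison. The lists share 0 genes. Members differed within each list: Akr1b7, a CAR and PXR target, had a value of 0.20 ± 0.24 at 200 mg/kg and rose by 3.78 ± 0.25 at 2000 mg/kg, and Abcc3, an NRF2 target, rose by 3.11 ± 0.13 and 4.40 ± 0.14.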
